A study of Homo sapiens with 4 samples.

How the data were processed

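Total RNA of Huh7.5 and Huh7.5M cells was measured on custom human Agilent arrays of oligonucleotide probes. Per the labels' protocols, cells grown to near confluence were trypsinised and washed in buffer containing cycloheximide, an inhibitor of translation elongation. RNA was then reverse transcribed with an oligo-dT primer and labelled with Cy3 by in-vitro transcription. Polysomal RNA, which the labels also describe, was not analysed here. Samples were grouped by the line named in the labels, with 2 arrays per line.

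The scanner files hold a processed signal per spot, an intensity on a linear scale that Agilent Feature Extraction (11.5.1.1) had already background-subtracted, per the file headers, together with flags for outliers, saturation and signal well above background. The array grid carries the build hg18, per the file headers. The deposited value table holds log2 values. Set against the scanner files, each column equalled the log2 processed signal minus a constant close to the array's 75th percentile. Slopes were 1.00, 99.7% to 99.8% of probes agreed within 0.001, and the constants differed from the percentile computed here by 0.0242 to 0.0473. The medians of its columns were −3.39 and −3.29 for Huh7.5 replicates 1 and 2 and −3.60 and −3.37 for Huh7.5M replicates 1 and 2. The scale is therefore known, genes were not centred, and the columns are single arrays with no direction. The constant's exact origin is not given in the sources used here. The table served as an alternative only.

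For the main setting, log2 of the processed signal minus the array's 75th percentile over non-control probes was computed from 51538 non-control spots per array (1319 control spots left out), in R 4.3.3 with data.table (1.17.8). Spots flagged as outliers were removed (30 to 50 per array), and spots of the same probe were averaged, giving 50238 probes. Names came from the probe's accession for 28595 probes, through a RefSeq gene table of assembly GRCh38.p14, from a current symbol for 2998, and stayed as in the file for 18645. That table was used only for names and for the chromosome of a gene, and no coordinates are given because its build differs from the array's. A gene was represented by its brightest probe among the 32419 probes well above background on both arrays of at least 1 line, which gave 21615 tested genes, 14705 of them with an official symbol. A gene counted as dim in a line only if all its probes were.

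Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all tested genes), with the line as the only term. Lists and chromosomes (at least 5 and 20 tested genes) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Camera compares a list with all other genes. Members were also counted adjusted over the list alone. The Y chromosome was left out. The 43 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest called increase and decrease that had an official symbol and the same side on both slides, up to 4 members by smallest p of each list that passed and up to 2 of the others, 16 genes fixed in advance, and the largest bounds among genes seen in a single line, up to 3 per line. Some named genes are not reported here. The fixed genes reported were the RIG-I gene, CD81, CLDN1, OCLN, SCARB1, ALB, AFP, APOE, HNF4A, EEF1A1, EEF1A2, EEF2, ABCB1, GAPDH and ACTB.

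The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the deposited log2 table, no filter on dim probes, a filter for signal well above background on all 4 arrays, the mean of a gene's probes, eBayes with trend and robust settings (statmod 1.5.0), the replicate number as a block, the fit within each slide, each array left out in turn, and for lists the rotation test fry. The procedure was tested on simulated data for the comparison of Huh7.5M with Huh7.5 over 21615 genes (20 simulations). With 5000 changed genes it recovered 8.06% of those changed 2-fold, 65.5% at 4-fold, 97.6% at 16-fold and 99.8% at 256-fold, and 3.71% of calls were false. With 200 changed genes it recovered 0% at 2-fold, 1.1% at 4-fold, 69.6% at 16-fold and 98.4% at 256-fold, and 4.84% of calls were false. A list of 30 genes shifted by 1 log2 unit had an unadjusted camera p under 0.05 in 20 of 20 simulations. The simulated genes varied independently and without a slide effect. The simulation therefore does not show how often a list of correlated genes would pass the adjusted threshold. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.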

Results

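Total RNA from Huh7.5 and Huh7.5M cells was hybridised to 4 single-colour Agilent arrays carrying 50238 non-control probes. Huh7.5 is a subline of the human hepatoma line Huh7 that supports replication of hepatitis C virus (HCV), and the labels describe it as sensitive to geneticin, an aminoglycoside that blocks protein synthesis in eukaryotic cells. Huh7.5M is described as resistant to geneticin, and the labels used here do not say how it was derived. Each line had 2 arrays, and each of the 2 slides held an array of each line. The share of probes well above background was 68.6% and 58.7% in Huh7.5 replicates 1 and 2 and 65.8% and 59.9% in Huh7.5M replicates 1 and 2. The 75th percentile of the processed intensity was 689 and 695 in Huh7.5 and 1131 and 814 in Huh7.5M, and no spot was saturated. Across the 21615 genes tested, which are not independent replicates, Pearson's r was 0.965 between the replicates of each line and lay between 0.736 and 0.766 for arrays of different lines. The number of arrays (4) limits the precision, and because the labels do not say whether the arrays of a line came from separate cultures, p-values measure only the spread between these samples, which may be technical.

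The comparison asks which transcripts differ between the geneticin-resistant and the geneticin-sensitive line. Several transcripts of secreted liver proteins that were among the brightest on the Huh7.5 arrays were near or below the detection limit on the arrays labelled Huh7.5M, with APOA1, APOA2, TTR and AFP among them. Of 24 genes of antigen presentation, 16 were higher on the Huh7.5M arrays and none lower. With limma, 5476 of the 21615 genes (25.3%) passed a Benjamini-Hochberg adjusted p of 0.05, of which 2711 were higher and 2765 lower in Huh7.5M (n = 2 per line). All 5476 lay on the same side on both slides. With 2 arrays per line this follows from the test, since slides of opposite sign would make the spread too large for a call. It is no separate evidence. The smallest called difference was 1.31 on the log2 scale, so each call exceeded 2-fold. Of the called genes, 2794 were well above background on all 4 arrays, with 1263 higher and 1531 lower. Without Huh7.5 replicate 2 the count was 3246 (1721 higher, 1525 lower), and with only genes well above background on all 4 arrays entering the test it was 2622 (1189 higher, 1433 lower).

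Signal in a single line was seen for 2 sets of genes, which overlap the called genes: 1068 genes were well above background on both Huh7.5 arrays and on neither Huh7.5M array (836 of them called), and 1054 genes showed the reverse (913 called). For these only a bound of the fold was available. It was the mean of the bright line over the mean, in the dim line, of the higher of each array's lowest signal well above background and the probe's own signal, and it is written below as "at least". The median bound was 5.31-fold for genes seen in Huh7.5 only and 5.48-fold for genes seen in Huh7.5M only. The bound reached 100-fold for 118 genes of the first set and 56 of the second. The second set held 22 genes whose bound did not exceed 1, for which no fold is given. With the scanner's less strict flag for signal above background, the 2 sets held 523 and 366 genes.

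Liver products, most of them secreted, were prominent among the largest decreases. RBP4 (plasma retinol carrier) was at least 6382-fold lower in Huh7.5M, AMBP (the precursor of alpha-1-microglobulin and bikunin) at least 8889-fold, APOA2 (an apolipoprotein of high-density lipoprotein) at least 5233-fold, and FABP1 (liver fatty acid-binding protein) at least 4338-fold. TTR was at least 3828-fold lower, AFP at least 3590-fold, APOA1 at least 2395-fold and APOH at least 1480-fold. The 12 genes with the largest decreases also included COL2A1, a fibrillar collagen (at least 2515-fold), and SPINK1, a trypsin inhibitor (at least 3655-fold). ALB had log2 values of 8.25 and 8.05 on the Huh7.5 arrays but −6.46 and −2.17 on the Huh7.5M arrays, where only replicate 2 was well above background (log2 fold change −12.46 ± 1.28 SE, limma adjusted p = 0.001). Among genes measured on both sides, chosen after their values were seen, AHSG was lower by a log2 fold change of −11.10, TF of −11.09, FGG of −10.53, ORM1 of −10.51 and APOE of −9.76.

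The largest increases were of genes of varied function. MAGED1, a member of the MAGE family, had a probe at least 2449-fold higher in Huh7.5M, and its second probe, well above background on 1 Huh7.5 array, gave a log2 fold change of 8.92. HOXB6 and HOXB13, homeobox transcription factors, had probes at least 798-fold and 329-fold higher. Their second probes gave 4.26 and 6.67 on the log2 scale. NMU (the neuropeptide neuromedin U) was at least 540-fold higher, PJA1 (a ubiquitin ligase) at least 417-fold, RTL6 at least 380-fold, MAGEA2B at least 573-fold and IFITM1 (an interferon-induced membrane protein) at least 562-fold. A probe of HK1, a hexokinase, was at least 250-fold higher, while another probe of HK1 was dim on 3 of the arrays. PFKP, the platelet phosphofructokinase, had a log2 fold change of 9.98 ± 0.45 (SE) and was well above background on 1 of the 2 Huh7.5 arrays. Genes measured on both sides and chosen after their values were seen included SPINT2 (9.30), LDHB (8.82), HOXB9 (8.60) and PRKCZ (8.56). The adjusted p was at most 0.000175 for each of the 12 genes with the largest increases, and at most 0.001 for each of the 12 with the largest decreases.

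**Figure D1:**
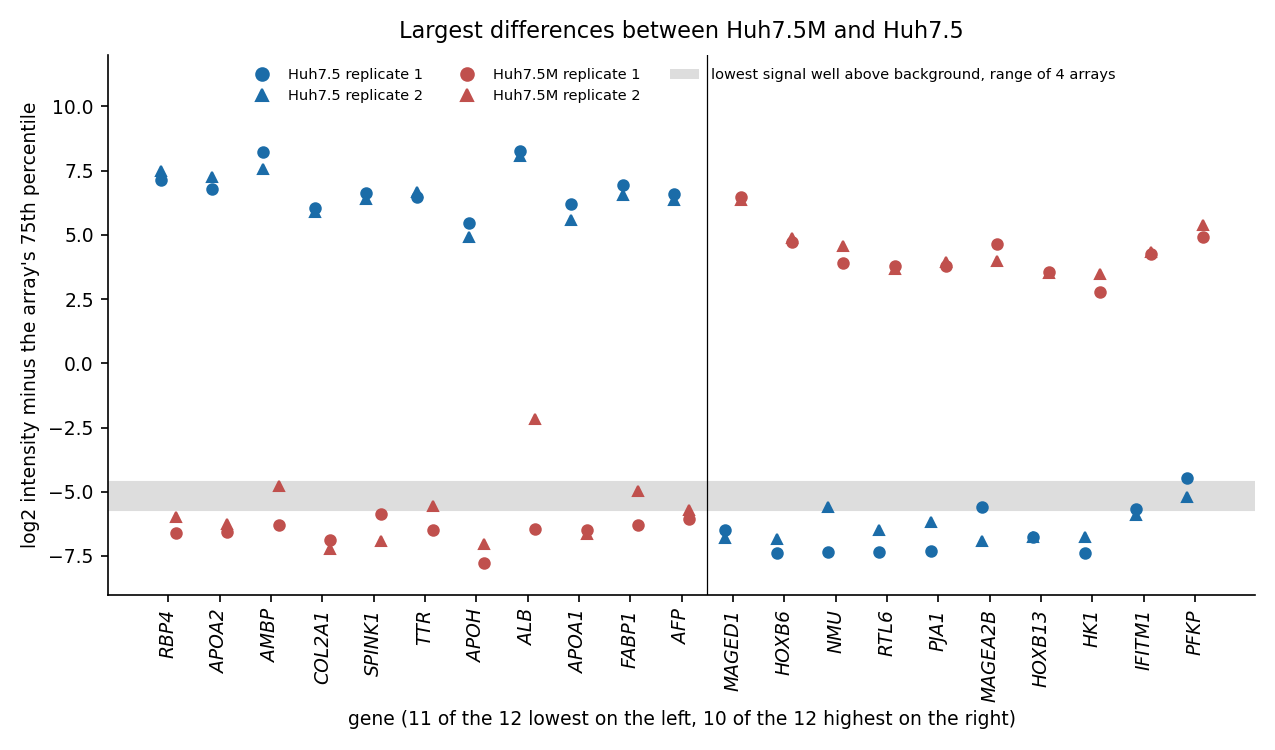
Log2 processed intensity minus the array's 75th percentile (vertical axis) for 11 of the 12 genes with the largest called decrease and 10 of the 12 with the largest called increase (horizontal axis); each point is an array, coloured by line and shaped by replicate, and the grey band spans the lowest signal well above background on the 4 arrays. Most low points lie within or below the band and so have no order, while ALB on Huh7.5M replicate 2 lies above it at −2.17.

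Lists of genes fixed before the data were examined were compared with all other genes by limma's camera test, with a preset correlation of 0.01 between genes. Of the 43 lists, 17 passed an adjusted p of 0.05, with 14 lower and 3 higher in Huh7.5M. None passed with a correlation estimated from the 4 arrays (smallest adjusted p = 0.339), and the adjusted p of this form is given beside each list. In this form camera rests on 2 residual degrees of freedom, so few lists could pass whatever their shift. Xenobiotic metabolism failed in it although its estimated correlation (−0.010) lay below the preset 0.01. A failure in this form therefore decides little, for lists and for chromosomes. Members named because they ran against their list, or because few members were called, were chosen after their values were seen.

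Of the 44 tested genes for proteins secreted by hepatocytes, 42 were lower and 1 was higher in Huh7.5M (the same counts adjusted over the list alone), with a median log2 fold change of −9.57 and of −9.27 with dim genes at their bound (camera adjusted p = 6.36e-27; adjusted p = 0.339 with an estimated correlation). The exception was ITIH4, with a log2 fold change of 2.47. Of 23 hepatocyte transcription factors, 15 were lower and none higher (16 lower adjusted over the list alone; median −3.52; camera adjusted p = 2.52e-08; adjusted p = 0.339 with an estimated correlation). NR1H4, the bile acid receptor, was at least 430-fold lower and NR0B2, its target repressor, at least 114-fold lower. HNF4A, a regulator of hepatocyte identity, had a log2 fold change of −2.34 ± 0.61 (SE, limma adjusted p = 0.0358). Its probe was low in both lines, with means of −2.29 in Huh7.5 and −4.63 in Huh7.5M. The latter is near the lowest signal well above background on the Huh7.5M arrays (−5.71 and −4.96), so the size of the fold is uncertain. The limma call of HNF4A was lost with normexp background correction (−1.32, adjusted p = 0.0564), without the filter on dim probes (0.0652) and with the mean of a gene's probes (0.0561). It was also lost without Huh7.5 replicate 1 (log2 fold change −2.74), Huh7.5 replicate 2 (−1.93) or Huh7.5M replicate 1 (−1.60). A second probe with −2.75 was not called.

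Lists of liver metabolism and transport passed as lower in the main setting. In the xenobiotic metabolism list 22 of 40 genes were lower and 1 was higher (25 and 2 adjusted over the list alone), with a median of −2.91, or −2.56 with bounds (adjusted p = 2.29e-07; adjusted p = 0.339 with an estimated correlation). ALDH1A1, a retinaldehyde dehydrogenase, had a log2 fold change of −7.19, UGT2B10, a glucuronosyltransferase, of −5.91, and ADH6 was at least 23.2-fold lower. CYP2E1 was at least 9.51-fold higher. Of 23 drug and bile transporters, 14 were lower and 1 was higher (15 and 2 adjusted over the list alone; median −3.15, or −2.73 with bounds; adjusted p = 0.000105; adjusted p = 0.428 with an estimated correlation). SLCO2B1 and SLCO1B3, which take up organic anions, were at least 94.3-fold and 76.1-fold lower, ABCC2 had a log2 fold change of −6.43, and ABCG1 was at least 18.0-fold higher. The transporter call was lost among genes well above background on all 4 arrays (median −0.84, adjusted p = 0.0749). In gluconeogenesis and amino acid catabolism 16 of 37 genes were lower and 1 was higher (19 and 1 adjusted over the list alone; median −1.46; adjusted p = 0.000217; adjusted p = 0.543 with an estimated correlation). ARG1 (the liver arginase) was at least 776-fold lower and HGD had a log2 fold change of −10.95, whereas CPS1, of the urea cycle, had 2.61.

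In the cholesterol biosynthesis list 13 of 29 genes were lower and none higher (16 lower adjusted over the list alone; median −1.19; adjusted p = 0.000244; adjusted p = 0.339 with an estimated correlation). MVD, of the mevalonate pathway, had a log2 fold change of −2.93. DHCR7 (−2.56) and FDPS (−2.29) lost their calls without Huh7.5 replicate 2 (adjusted p = 0.0698 and 0.0694). In fatty acid and triglyceride metabolism 15 of 46 genes were lower and 2 higher (17 and 3 adjusted over the list alone; median −0.95; adjusted p = 0.00243; adjusted p = 0.339 with an estimated correlation). FADS2, a fatty acid desaturase, had −4.77 and GPAM −2.55 (−1.05 and not called at a second probe), while G0S2 (6.11) and SCD5 (3.74) were higher. Imprinted and fetal liver genes also fell, with 16 of 26 lower and 1 higher (17 and 1 adjusted over the list alone; median −1.83; adjusted p = 8.93e-06; adjusted p = 0.339 with an estimated correlation). PEG10, a retrotransposon-derived imprinted gene, was at least 163-fold lower, and KIT was at least 32.2-fold higher.

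**Figure D2:**
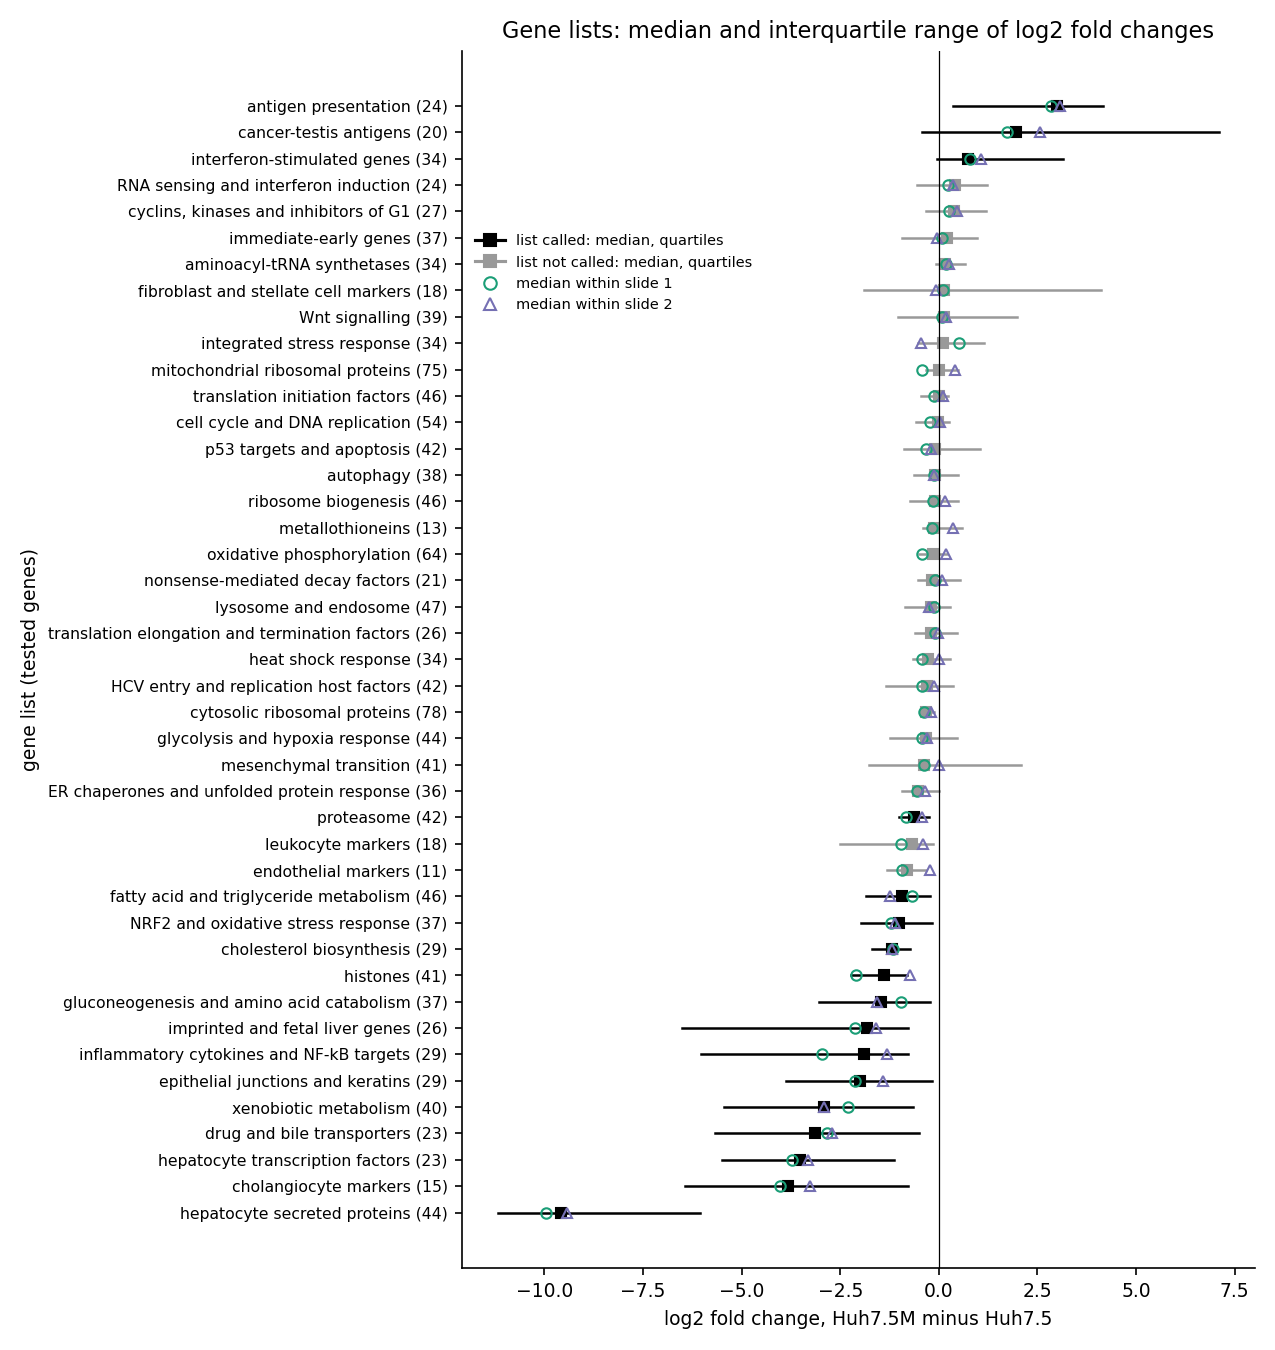
Median log2 fold change, Huh7.5M minus Huh7.5 (horizontal axis), of each of the 43 gene lists (vertical axis, tested genes in parentheses). Squares are medians and lines the quartiles, black for lists called by camera with the preset correlation, and open symbols are the medians within each slide. Hepatocyte secreted proteins lie lowest, at −9.57, and antigen presentation highest, at 2.99.

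Lists of epithelial, inflammatory and oxidative stress genes also passed as lower. Of 29 genes of epithelial junctions and keratins, 14 were lower and none higher (14 adjusted over the list alone; median −1.99; adjusted p = 0.000105; adjusted p = 0.428 with an estimated correlation). CLDN1, a tight junction protein and HCV entry factor, had a log2 fold change of −8.84 ± 0.53 (SE), ESRP2, an epithelial splicing regulator, of −6.97, and KRT23 was at least 189-fold lower. The list's median was −1.22 without Huh7.5 replicate 2 and −1.14 without Huh7.5M replicate 1, and its call held. Of 29 inflammatory cytokines and NF-kB targets, 12 were lower and none higher (16 lower adjusted over the list alone; median −1.90; adjusted p = 0.000105; adjusted p = 0.629 with an estimated correlation). The members with the smallest p included C3 (−10.31), a complement gene that the liver makes, and the chemokine CCL20 (at least 174-fold lower). In the NRF2 and oxidative stress list 15 of 37 genes were lower and 1 was higher (16 and 1 adjusted over the list alone; median −1.01; adjusted p = 0.000423; adjusted p = 0.339 with an estimated correlation). AKR1C1 and AKR1C3, aldo-keto reductases, had −6.69 and −4.39, though closely related AKR1C copies may share probes, and AKR1B1 had 3.26.

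Histone transcripts fell in 12 of 41 genes and rose in none (15 lower adjusted over the list alone; median −1.39; adjusted p = 6.11e-05; adjusted p = 0.736 with an estimated correlation). The median was −2.10 on slide 1 and −0.73 on slide 2, and the list did not pass the rotation test fry (adjusted p = 0.142). H2BC12 had −4.23 and H2BC5 −2.35, and near-identical histone genes leave the assignment of each probe uncertain. Of 42 proteasome genes, 5 were lower and 3 higher (2 and 2 adjusted over the list alone; median −0.62; adjusted p = 0.0461; adjusted p = 0.867 with an estimated correlation). PSMD5, an assembly chaperone, was at least 179-fold lower, with PSMC2, PSMD14, PSMC4 and PSMD1 lower by smaller amounts and PSMD6, PSMB9 and PSMD10 higher. PSMC4 and PSMD1 lost their calls when any array was left out (adjusted p between 0.0573 and 0.186), and PSMC2 in all cases but that of Huh7.5M replicate 1. The proteasome call did not hold with fry (adjusted p = 0.118), nor in camera with the slide as a block (0.0652), after quantile normalization (0.222) or median scaling (0.0708). Camera also lost it with normexp background correction (0.0566), without the filter on dim probes (0.122), with signal required on all 4 arrays (0.0517) and with the mean of a gene's probes (0.0860). It was lost too without Huh7.5 replicate 1 (median −0.53), Huh7.5M replicate 1 (−0.56) or Huh7.5M replicate 2 (−0.78).

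Of 24 tested genes of antigen presentation, 16 were higher in Huh7.5M and none lower (16 higher and 2 lower adjusted over the list alone), with a median of 2.99, or 2.80 with bounds (adjusted p = 1.48e-06; adjusted p = 0.339 with an estimated correlation). TAP1, the peptide transporter of the class I pathway, was at least 255.6-fold higher, ERAP2, a peptide-trimming enzyme, had a log2 fold change of 6.52 with 1 of 2 Huh7.5 arrays well above background, and MICA, a stress ligand, had 4.18. HLA-DPA1 was at least 9.05-fold higher. HLA genes are near-identical copies, so probes may cross-hybridise and single members stay uncertain.

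Of 20 cancer-testis antigens, whose normal expression is largely limited to germ cells, 11 were higher and none lower (12 adjusted over the list alone; median 1.96; adjusted p = 4.92e-05; adjusted p = 0.339 with an estimated correlation). MAGEA12 was at least 198-fold higher, CSAG2 at least 47.2-fold and MAGEA4 at least 15.7-fold; members of the MAGEA family are close copies and may share probes. Without the filter on dim probes the median was −0.21, and among genes well above background on all 4 arrays it was −0.06 and the call was lost (adjusted p = 0.489), since most called members were dim in Huh7.5.

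Interferon-stimulated genes moved both ways, with more higher than lower. Of 34 tested, 13 were higher and 3 lower (16 and 3 adjusted over the list alone; median 0.75; adjusted p = 0.00161; adjusted p = 0.459 with an estimated correlation). A probe of SAMD9 was at least 10.6-fold higher and a probe of HERC6 at least 14.9-fold. The other SAMD9 probes were well above background on no array, and the second HERC6 probe on only 1 Huh7.5M array. IFI6 had 4.06 at its brighter probe and −0.30 at a second probe that was not called. The interferon-stimulated members that fell were MX2 (at least 521-fold lower), MX1 (−2.97) and ISG20 (−2.46). Among 24 genes of RNA sensing and interferon induction, 5 were higher and 3 lower (5 and 3 adjusted over the list alone), and the list did not pass (median 0.41, adjusted p = 0.215; 0.046 with fry). RNF135, a ubiquitin ligase acting on the sensor RIG-I, had a probe at least 113-fold higher, and STING1, IFIH1 and DHX58 were also higher. TICAM1, the adaptor of the receptor TLR3, had a probe at least 202-fold lower, with SOCS1 and IFNAR2 lower. RIGI, the RNA sensor that is defective in Huh7.5, had a log2 fold change of 0.14 ± 0.38 (SE, adjusted p = 0.825).

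HCV entry and replication host factors were mixed. Of 42 tested, 8 were lower and 5 higher (9 and 5 adjusted over the list alone; median −0.30), and the list did not pass (adjusted p = 0.308). APOE, an apolipoprotein of the viral particle, was lower by 865-fold and MTTP, which loads lipid onto lipoproteins, had −9.02 with 1 of 2 Huh7.5M arrays well above background. Among the entry factors, CLDN1 was 459-fold lower, while CD81 had a log2 fold change of 0.83 (adjusted p = 0.199) and OCLN of −0.05 (adjusted p = 0.942; 0.09 after median scaling). SCARB1 (−1.43, adjusted p = 0.0393) lost its call when any of the 4 arrays was left out (adjusted p = 0.133 and 0.099 without Huh7.5 replicates 1 and 2, 0.142 and 0.104 without Huh7.5M replicates 1 and 2), and its 2 other probes were not called (−1.11 and −1.08). The factors that were higher were SEC14L2, SPCS1, FBXL20, HRAS and AGO2, by 1.41 to 2.69 on the log2 scale.

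Geneticin acts on translation, and the translation lists did not pass in the main setting. None of the 78 cytosolic ribosomal protein genes was called (median −0.33, adjusted p = 0.267; median 0.05 after quantile normalization). Without Huh7.5 replicate 2 the list passed as lower (median −0.48, adjusted p = 0.0384). Of 46 translation initiation factors, EIF4E3 (2.08) and EIF4EBP2 (−1.60) were called (list median −0.01, adjusted p = 0.908). EIF4E3 lost its limma call without the filter on dim probes (adjusted p = 0.0705). It was also lost without Huh7.5 replicate 1 (log2 fold change 2.45), Huh7.5 replicate 2 (1.72) or Huh7.5M replicate 1 (1.48). However, 2 other probes of EIF4E3 gave 3.17 and 4.57 (adjusted p = 0.00211 and 0.002 among probes). EIF4EBP2 lost its call with normexp background correction (adjusted p = 0.0814), after quantile normalization (0.0526) and without the filter on dim probes (0.0677). Its call was also lost without Huh7.5 replicate 1 (log2 fold change −1.53), Huh7.5 replicate 2 (−1.67) or Huh7.5M replicate 2 (−1.45). Of 26 elongation and termination factors, EEF1A2, the isoform of the elongation factor found mainly in neurons and muscle, was called, with a log2 fold change of 5.92 ± 0.39 (SE, adjusted p = 0.000206) and 1 of 2 Huh7.5 arrays well above background. EEF1A1, the widespread isoform, had −0.21 (adjusted p = 0.747; 0.23 after quantile normalization and 0.07 without Huh7.5 replicate 1), and EEF2 had −1.08 (adjusted p = 0.300). ABCB1, a drug efflux pump, had −2.73 ± 0.42 (SE, adjusted p = 0.00518). The lists of mitochondrial ribosomal proteins (75 genes, 1 higher and 1 lower), aminoacyl-tRNA synthetases (34, 1 higher), ribosome biogenesis (46, 1 higher) and nonsense-mediated decay factors (21, 1 higher) had adjusted p of 0.723, 0.215, 0.968 and 0.968. Without the filter on dim probes the aminoacyl-tRNA synthetases passed as higher (median 0.17, adjusted p = 0.0448). None of these members was called when adjusted over the list alone, and neither were the initiation factors, while EEF1A2 was. With the slide as a block more members were called, with 4 higher and 4 lower for mitochondrial ribosomal proteins, 3 and 0 for aminoacyl-tRNA synthetases, 3 and 3 for ribosome biogenesis, 2 and 3 for nonsense-mediated decay, 4 and 3 for initiation factors and 1 and 1 for elongation factors.

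Other lists contained large changes in opposite directions. In glycolysis and the hypoxia response 7 of 44 genes were higher and 10 lower (8 and 12 adjusted over the list alone; median −0.34, adjusted p = 0.723), HK1 and PFKP rising as above. In the mesenchymal transition list 12 of 41 were higher and 10 lower (12 and 11 adjusted over the list alone; median −0.37, adjusted p = 0.670), with TIMP1, a metalloproteinase inhibitor, at least 156-fold higher and TGFBI, an extracellular matrix protein, at −11.69 with 1 of 2 Huh7.5M arrays well above background. In Wnt signalling 13 of 39 were higher and 6 lower (14 and 8 adjusted over the list alone; median 0.12, adjusted p = 0.437). The secreted Wnt antagonists SFRP1 and DKK1 moved apart, at least 180-fold higher and −6.26. Among cyclins, kinases and inhibitors of G1, 7 of 27 were higher and 2 lower (7 and 3 adjusted over the list alone; median 0.37, adjusted p = 0.215, but 0.0453 and called without the filter on dim probes), with MYCN at −6.46 (a dimmer second probe had −0.85 and was not called) and CCND3 at 2.76. The cell cycle and DNA replication list had a single call in 54 genes, E2F2 (1.45, with 0.36 at a second probe that was not called), which was lost when any array was left out (adjusted p between 0.0783 and 0.159), and none adjusted over the list alone (median −0.03, adjusted p = 0.996). The p53 and apoptosis list had 5 of 42 higher and 5 lower (the same adjusted over the list alone; adjusted p = 0.878), with PHLDA3 at 4.87 and BCL2L1 at −3.55. Immediate-early genes had 6 of 37 higher and 7 lower (6 and 8 adjusted over the list alone; adjusted p = 0.877), with DUSP6, a phosphatase of ERK, at −7.77.

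The remaining stress and organelle lists held few calls. The integrated stress response had 5 of 34 genes higher and 2 lower (3 and 2 adjusted over the list alone; adjusted p = 0.584), with DDIT4 at 2.66 and GDF15 at −4.53, and its median was 0.51 on slide 1 and −0.45 on slide 2. Endoplasmic reticulum chaperones had 1 of 36 higher, DERL3 (4.36), and 5 lower (1 and none adjusted over the list alone; adjusted p = 0.215). The heat shock list had 2 of 34 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.831). The lower member, HSPA1A, had −6.73 at its brightest probe but 0.63 and 0.51 at 2 other probes, and it has a near-identical copy, HSPA1B, which was called higher. Lysosome and endosome genes had 3 of 47 higher and 2 lower (none and 2 adjusted over the list alone; adjusted p = 0.723, but 0.046 with fry), and CTSZ, a cathepsin, was at least 171-fold lower. Autophagy genes had 2 of 38 higher and 2 lower (1 and none adjusted over the list alone; adjusted p = 0.908), with ULK2 at 4.89. Metallothioneins had 1 of 13 lower, MT1M (also adjusted over the list alone; adjusted p = 0.968), whose call was lost without Huh7.5 replicate 1 (adjusted p = 0.0918) or Huh7.5 replicate 2 (0.122). Oxidative phosphorylation had 1 of 64 lower, NDUFV1 (−1.43), lost when any array was left out (adjusted p between 0.0918 and 0.143), and none adjusted over the list alone (adjusted p = 0.836). For 10 of the lists that did not pass, the median, the mean and the camera direction did not share a sign: initiation factors, elongation factors, ribosome biogenesis, nonsense-mediated decay, autophagy, metallothioneins, p53 targets, cell cycle, mesenchymal transition and immediate-early genes. After quantile normalization or median scaling, the medians of initiation factors, ribosome biogenesis, cell cycle, oxidative phosphorylation and p53 targets lay above 0. The housekeeping genes GAPDH (−0.69, adjusted p = 0.270) and ACTB (−1.66, adjusted p = 0.139) were not called, though ACTB was with the slide as a block (adjusted p = 0.0213). ACTB had −2.63 without Huh7.5M replicate 1 (adjusted p = 0.00165), and its 3 other probes gave 0.11 to 0.35.

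Markers of other cell types did not move together. Of 15 cholangiocyte markers, 10 were lower and 1, MUC1, was higher (10 and 1 adjusted over the list alone; median −3.82, or −3.46 with bounds; adjusted p = 0.000231; adjusted p = 0.459 with an estimated correlation). CD24 (−7.52) and PROM1 (at least 72.1-fold lower) stand in both this list and the fetal liver list, and KRT19, a biliary keratin, was at least 84.8-fold lower. Fibroblast and stellate cell markers had 7 of 18 higher and 5 lower (7 and 6 adjusted over the list alone; median 0.13, adjusted p = 0.424, but 0.0163 with fry), with the collagen gene COL1A1 at least 23.3-fold higher and COL1A2 at least 7.80-fold lower. Leukocyte markers had 3 of 18 higher and 5 lower (the same adjusted over the list alone; median −0.69, adjusted p = 0.267), with LYZ, lysozyme, at least 131-fold lower. Endothelial markers had FLT1 higher and PECAM1 lower among 11 tested (1 and 3 adjusted over the list alone; median −0.81, adjusted p = 0.367).

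Genes of chromosome X were shifted upward in Huh7.5M. The 534 tested X genes had a median log2 fold change of 1.04 (0.98 with bounds) against −0.09 for 14147 autosomal genes, with 200 higher and 47 lower (camera adjusted p = 1.34e-11; adjusted p = 0.842 with an estimated correlation). The median was 0.99 on slide 1 and 1.11 on slide 2, and 0.89 over the 376 X genes well above background on all 4 arrays. No autosome passed, the closest being chromosome 22 (median 0.27, adjusted p = 0.0610) and chromosome 16 (0.19, adjusted p = 0.0884). Chromosomes 16 and 22 did pass, beside X, without Huh7.5 replicate 2, without the filter on dim probes and with signal required on all 4 arrays, and chromosome 22 after quantile normalization.

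**Figure D3:**
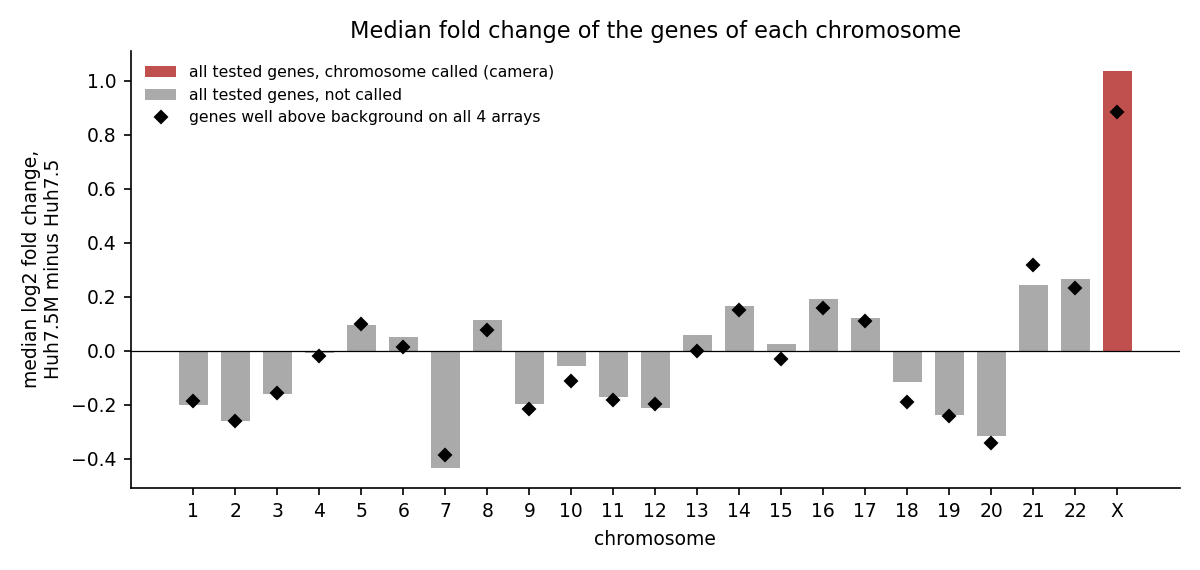
Median log2 fold change, Huh7.5M minus Huh7.5 (vertical axis), of the tested genes of each chromosome (horizontal axis); bars are medians over all tested genes, red where camera called the chromosome, and diamonds are medians over genes well above background on all 4 arrays. Chromosome X stands at 1.04 and every autosome between −0.43 and 0.27.

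The slides were compared as a batch that held both lines. With the slide in place of the line, limma called 0 genes (397 at an unadjusted p of 0.05). That fit leaves the difference between the lines in its residual, so it could find little. With the line kept as a second term limma called 48 genes, of which 9 were higher and 39 lower on slide 2. In that fit 3268 genes had an unadjusted p under 0.05, so a slide effect was present. The differences between the lines on the 2 slides correlated across genes with r = 0.91.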

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

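The direction of the main result did not turn under any setting tried: no called gene was called in the opposite direction. All settings drew on the same 4 arrays, and the smallest called difference was 1.31 on the log2 scale. Opposite calls could therefore hardly occur, and their absence is no separate evidence. Of the 5476 called genes, 93.9% were called in the same direction after quantile normalization (5455 calls, 2958 higher and 2497 lower), 93.9% after median scaling (5378; 2924 and 2454), 76.7% with normexp background correction (4636), 99.6% on the deposited log2 values (5477), 96.1% with the mean of a gene's probes (5803), 95.4% with trend and robust settings (5674) and 73.5% without the filter on dim probes (4250). With signal well above background required on all 4 arrays, 2622 genes were called in total and again at 2-fold or more, 2620 of them main calls. Only 2838 of the main calls could be tested there, so fewer tested genes account for much of the drop. With an array left out, limma took the lone array to vary like the other line, and 3246 to 5866 genes were called (3246 to 5866 at 2-fold or more), with the fewest without Huh7.5 replicate 2 and the most without Huh7.5M replicate 2. The median log2 fold change of all tested genes was −0.18, against −0.04 after median scaling and −0.03 after quantile normalization, and folds are to be read relative to it.

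The replicate number marks the slide, per the file headers, so it was fitted as a block. Deviations of same-numbered arrays from their line's mean correlated with r = 0.40 across genes. The fit with this block called 7679 genes (3581 higher, 4098 lower), which contained all 5476 main calls, and 16 lists. Each slide held an array of each line, so the block leaves every fold change as it was and no direction could turn. Among 141 named genes the block added 8 calls and ended none, and the proteasome was the sole list whose call it changed. The slide effect itself gave 48 calls in the limma fit with the line as a second term (3268 genes at an unadjusted p under 0.05). It gave 0 calls alone, where the difference between the lines stays in the residual.

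Between 14 and 18 lists passed with the preset correlation, 18 with fry and 0 with an estimated correlation. The last form rests on 2 residual degrees of freedom, so few lists or chromosomes could pass in it. Fry lost histones and the proteasome, and added RNA sensing (up), lysosome and endosome (down) and fibroblast markers (up). Chromosome calls were 1 in the main setting, 2 after quantile normalization, 3 without the filter on dim probes, 3 with signal required on all 4 arrays, 1 to 3 with an array left out and 0 with an estimated correlation. Genes seen in a single line numbered 2122, 889 with the flag for positive and significant signal, and 2956 when any probe sufficed. Over all settings, 1840 of 2037 gene values and 561 of 645 list values kept their direction and their side of the threshold, or moved within the replicate spread where the value had no test.

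Apart from cancer-testis antigens, the values that turned sign belonged to genes and lists that were not called in the main setting, and the cause was not tested. With normexp the medians were −0.0099 for mitochondrial ribosomal proteins, 0.047 for initiation factors and −0.13 for fibroblast markers. After quantile normalization they were 0.051 for cytosolic ribosomal proteins, 0.26 for initiation factors, 0.10 for ribosome biogenesis, 0.045 for p53 targets, 0.11 for cell cycle and 0.18 for oxidative phosphorylation, and EEF1A1 had 0.23. After median scaling they were 0.14 for initiation factors, 0.046 for ribosome biogenesis, 0.048 for autophagy, 0.029 for metallothioneins, 0.052 for p53 targets, 0.11 for cell cycle and 0.0045 for oxidative phosphorylation, and OCLN had 0.091. Without the filter on dim probes they were −0.11 for RNA sensing, −0.21 for cancer-testis antigens (still called up, adjusted p = 0.00054) and −0.14 for fibroblast markers. With signal required on all 4 arrays, where genes dim in a line drop out, they were 0.031 for metallothioneins, −0.49 for Wnt signalling, −0.057 for cancer-testis antigens (no longer called, adjusted p = 0.489) and −0.73 for fibroblast markers. With the mean of a gene's probes they were 0.013 for initiation factors, 0.034 for autophagy, 0.17 for metallothioneins, 0.24 for p53 targets and 0.033 for mesenchymal transition.

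With an array left out, values that turned sign ranged from −0.49 to 0.068 for EEF1A1, −0.33 to 0.23 for OCLN, −0.0195 to 0.29 for RIGI, −0.13 to 0.029 for autophagy, −0.21 to 0.064 for cell cycle, −0.23 to 0.41 for immediate-early genes, −0.37 to 0.28 for the integrated stress response, −0.046 to 0.058 for mesenchymal transition, −0.073 to 0.31 for metallothioneins, −0.30 to 0.31 for mitochondrial ribosomal proteins, −0.38 to 0.045 for oxidative phosphorylation, −0.22 to 0.11 for p53 targets, −0.30 to 0.080 for ribosome biogenesis, −0.26 to 0.014 for elongation factors and −0.23 to 0.11 for initiation factors. Signal over background limits the sizes, since for 1898 of the called genes the probe used was dim on both arrays of a line; counting all probes of a gene, these were 836 seen only in Huh7.5 and 913 only in Huh7.5M.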

Other observations

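The tests of array scaling, of both explanations for ALB and of both explanations for chromosome X were chosen only after the result was seen, and the HOX genes were singled out after their values were seen. The HOX clusters hold homeobox genes that set positional identity along the body axis, and they had no fixed list and no set test. Of 39 HOX genes on the array, 34 were tested, of which 22 were higher, 1 was lower and 11 were not called. The median log2 fold change was 2.88 (3.22 after quantile normalization, 2.12 on slide 1 and 3.75 on slide 2). All 34 were well above background on both Huh7.5M arrays, but only 17 on both Huh7.5 arrays. The others entered the test only through Huh7.5M and could hardly be called lower, which tilts these counts upward. The HOXB cluster had 8 of 9 tested genes higher, 7 of them dim on both Huh7.5 arrays at the probe used, such as HOXB5 (at least 108-fold higher), with HOXB7 not called. HOXD had 6 of 7 higher, among them HOXD10 (at least 98.8-fold), and HOXD1 lower (−3.54). HOXA had 7 of 11 higher, with HOXA5 at 4.45, while HOXA3 was bright in both lines and was not called (−0.14). HOXC had only HOXC13 higher (2.20) among 7.

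Of 44 tested transcripts of proteins secreted by hepatocytes, 42 were lower on the arrays labelled Huh7.5M, where 10 were still well above background on both, and 5476 genes were called in all. The choice among the scalings tried hardly bears on this pattern. Quantile normalization moved the median log2 fold change of all genes only from −0.18 to −0.03, while the smallest called difference was 1.31. That 93.9% of the called genes were then called in the same direction follows largely from these sizes, and is no separate evidence. Loss of hepatocyte identity within Huh7.5 cells cannot be told apart from other origins of this pattern, because genes seen only in Huh7.5 were 1.01 times as many as those seen only in Huh7.5M (1068 and 1054) and such a loss allows gains.

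What stays open is that the cultures labelled Huh7.5M may hold another cell line, a mix-up for which the human embryonic kidney line HEK293 or a relative is a candidate explanation. Its 2 marker lists were written before their values were seen, but after 1 listed gene had been seen to be low and with the geneticin resistance known from the labels. Of 17 tested genes that HEK293 cells express, 10 were higher, such as PAX2 (at least 31.6-fold), and 2 lower, CHRM3 (−4.40) and LIN28B (−2.37), and the median of 2.67 lay at percentile 100 of 10000 random lists matched on signal (95% between −0.80 and 0.53); the 3 not tested, SOX11, MAP2 and CRABP1, passed the signal filter in neither line, which counts against this candidate. Of 10 tested genes that these cells lack or hold low, without the gene seen before, 4 were lower, such as LGALS3 (−5.42). Another 2 were higher, STING1 (5.23) and CD44 (2.00), and the median lay at percentile 1.35. Yet 9 of the 10 were well above background on both Huh7.5M arrays, among them S100A10, although it was called lower (−2.48). Such signal counts against cells that lack these genes, but not against cells that hold them low. The 3 untested genes of this list passed the filter in neither line. The lists are short, have 4 tested members each in the lists of the report, include exceptions and do not separate HEK293 from other non-hepatic lines, so the arrays do not establish which cells were used; genotyping of short tandem repeats in the cultures would.

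ALB lay 4.30 higher on the log2 scale in Huh7.5M replicate 2 than in replicate 1. A trace of Huh7.5 RNA is argued against: at the share ALB sets, 15 other hepatocyte transcripts would rise by a median of 1.93, but observed minus computed rise had a median of −1.21 (upper quartile −0.69). An earlier measure, their median level in this array relative to Huh7.5 minus that of ALB (−0.75, upper quartile 0.30), was seen first and did not decide the question. It was replaced because most of these transcripts lay near the floor. The replacement shares this limit in part. In Huh7.5M replicate 1, transcripts such as AFP (−6.05) and RBP4 (−6.60) lay below that array's lowest signal well above background (−5.71). The test therefore weighs against a trace only weakly. A generally higher background is argued against too, since 11830 probes dim on every array were higher by a median of only 0.794. The difference rests on a single ALB probe and was not unique to it, as 135 probes lay more than 4 higher in replicate 2, so its origin stays open.

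Genes of chromosome X were shifted upward in Huh7.5M. The families set aside by name were MAGE, GAGE, XAGE, PAGE, SSX, SPANX, CT45, CSAG, BEX, TCEAL and CTAG. They held only 39 of the 534 tested X genes, so leaving them out could hardly move the median. Chosen by name, the 39 are not a count of germline genes. The 357 X genes outside them and above background on all 4 arrays had a median of 0.90. This was 0.99 above that of autosomal genes (−0.09), with a lower quartile 0.15 above it. The values show only that the shift was not confined to the families. That 79.6% of these genes lay above the autosomal median restates the shift, so more active copies of chromosome X cannot be told apart from other causes of it. Copy number was not measured.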
